A study of Mus musculus with 12 samples.

How the data were processed

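The samples were 12 RNA preparations from female C57BL/6 mouse pluripotent cells: embryonic stem cells (ESC) and induced pluripotent stem cells (iPSC), each divided by flow sorting on the dye TMRM into a low and a high membrane potential fraction. Each of the 4 groups held 3 arrays, which the labels number 2, 3 and 4. Neither the labels nor the design text say that equal-group arrays came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

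The deposited table holds log2 expression values made by the authors, 1 column per array and 25206 probe sets per column. Per the submitters' processing notes, the tools were RMA, affy 1.36.1 and R 2.15.1. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of each probe set on the log2 scale. The chip definition and the genome build behind the probe sets are not given in the sources used here. The values carry no detection calls, so a level cannot be set against background. Probe-level intensities were not used here. The number of arrays, not a read depth, limits the precision.

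Gene names came from the platform annotation. Of the 25206 probe sets, 23185 had 1 gene symbol, 0 had several and 2021 had none. All 23185 were found by gene number in a reference gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names, chromosome membership and gene order only. Probe sets of near-identical paralogs (histone H3 genes, Zscan4, Pramel, Oas1 and Eif4a3 relatives) can share signal between copies, and their values are uncertain as to the copy. Unnamed probe sets entered every test but are not named.

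All tests were run in R 4.3.3 with limma 3.58.1, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The model had 1 mean per group over all 12 arrays, with no block, moderated variances without a trend, and Benjamini-Hochberg adjustment over the 25206 probe sets of each comparison. The threshold was an adjusted p under 0.05. The comparisons were high minus low in ESC, high minus low in iPSC, the average of those, their difference (iPSC effect minus ESC effect), and iPSC minus ESC averaged over the fractions. Errors of log2 differences are standard errors from that fit, and errors of group means are SD of 3 arrays. Adjusted p-values in the text are limma's unless stated otherwise.

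Before the data were examined, 45 gene lists were written (mitochondrial functions, metabolism, stress, cell cycle, pluripotency, lineages, possible contaminating cells and others). A list needed 4 measured members. 44 were tested with camera, limma's competitive set test, at a preset correlation between genes of 0.01, adjusted over the 44 lists of a comparison. The list of genes encoded by mitochondrial DNA had 0 measured members and was not analysed here. Camera with an estimated correlation, camera on ranks and fry were alternatives, as was an exact sign-flip test over 6 high-low pairs, which was chosen after seeing the data.

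The rule for named genes was also fixed before the data were examined. It took, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap between the compared groups, leaving out predicted, clone-named, microRNA and small nucleolar RNA genes. It added up to 4 members with the lowest p from each list described, and a fixed set of pluripotency, lineage, metabolic, dye-transport and imprinted genes. For 3 arrays against 3, arrays do not overlap by chance in 10% of cases. Of the fixed set, T and Ucp2 were not analysed here. Genes outside the rule are said to be so where they appear.

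Whether replicate numbers pair the samples was checked before calls were compared. The residuals of the low and high arrays with equal number correlated at 0.34, 0.23 and 0.28 in ESC and at 0.11, 0.13 and 0.21 in iPSC, all above 0.1 and all above the correlations with other numbers. The numbers were therefore taken to pair the fractions within a cell type, an inference from the data. With the replicate block within each cell type, 146 probe sets were higher and 31 lower in ESC high. Between ESC and iPSC arrays of equal number the correlations ranged from -0.09 to 0.13, and those numbers were not taken as pairs. Blocked counts are printed where they differ from the unblocked by over 1.5 times.

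The fits were tested on simulated data with the observed spread, in which 67, 67 and 66 probe sets were changed by log2 amounts of 0.5, 1 and 2. The changed probe sets were drawn from those above the median level, so recovery of dimmer ones was not tested. Noise was independent between arrays, without the pairing. The rates for iPSC versus ESC therefore hold for independent arrays, not for paired ones. A log2 change of 0.5 was recovered for 38.8% of changed probe sets in the ESC comparison, 38.8% in iPSC, 71.6% in the average and 73.1% in iPSC versus ESC. A log2 change of 1 was recovered for 89.6%, 91.0%, 100% and 100%. For a change in iPSC alone, the test of the difference recovered 7.46% at a log2 change of 0.5, 65.7% at 1 and 90.9% at 2. All those runs tested 25206 probe sets.

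Alternatives fixed before the data were examined were the replicate block within and across cell types, a variance trend with a robust prior, removal of probe sets below the median level, quantile normalization, median centring, array weights, fits to 6 arrays only, a fold change of at least 1.5, an adjusted p under 0.01, named probe sets only and leaving out each array. Leaving out chromosomes 5 and 12 from iPSC versus ESC was added after seeing the data. So were fits of iPSC versus ESC that respect the pairs, with the replicate block as a random effect (duplicateCorrelation of limma, consensus correlation 0.192; 143 higher and 320 lower) or as 6 pair means (27 and 36). Chromosome medians used probe sets with a mean log2 level above 5, and each of the chromosomes discussed was divided into 10 blocks of neighbouring genes.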

Results

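Gene expression was profiled on Affymetrix arrays in mouse ESC and in iPSC, which are somatic cells reprogrammed to pluripotency. The cells were female, of C57BL/6 background, and grown undifferentiated in feeder-free 2iLIF medium. They were loaded with tetramethylrhodamine methyl ester (TMRM), a fluorescent cation that gathers in mitochondria in proportion to their membrane potential, and flow-sorted into a low and a high fraction. The design asks how the transcriptome differs with membrane potential in each cell type. Each of the 4 groups (ESC low, ESC high, iPSC low, iPSC high) held 3 arrays with 25206 probe sets. Array medians lay between 3.51 and 3.61 on the log2 scale. Pearson correlations across probe sets ranged from 0.991 to 0.994 within groups and from 0.986 to 0.994 between groups, and no arrays were identical.

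Over both cell types, cells of the high fraction had higher mRNA of G2 and mitosis genes and lower mRNA of G1/S genes and p53 target genes. The fractions are called low and high potential here, although the sort itself was on dye content. Of 25 measured G2/M genes, 17 rose, 0 fell and the others did not pass (21 rose when adjusted over the list alone), with a median log2 difference of 0.37. The mitotic kinase Aurka rose by 0.85 ± 0.09 (SE) on the log2 scale (adjusted p = 0.000448, limma) and Aurkb by 0.68 ± 0.07 (adjusted p = 0.000448, limma). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 0.71 ± 0.06, and the spindle protein Nusap1 by 0.70 ± 0.06. Of 21 measured G1/S genes, 0 rose and 4 fell (8 fell when adjusted over the list alone), with a median of -0.14. These were Ccne2, a cyclin of S-phase entry, at -0.74 ± 0.09, the replication licensing factor Cdc6 at -0.46 ± 0.08, the uracil-DNA glycosylase Ung at -0.51 ± 0.09, and the histone mRNA binding protein Slbp at -0.32 ± 0.07. Of 21 measured p53 targets, 7 fell and 0 rose (14 fell and 1 rose when adjusted over the list alone), with a median of -0.36. Trp53inp1 fell by 0.91 ± 0.10, the cyclin-like Ccng1 by 0.61 ± 0.09, Zmat3 by 0.51 ± 0.08 and Mdm2, the ubiquitin ligase of p53, by 0.45 ± 0.07. The camera test of limma called the G2/M list (adjusted p = 4.3e-29; adjusted p = 0.0495 with an estimated correlation), the p53 list (adjusted p = 2.08e-11; adjusted p = 0.0642 with an estimated correlation) and the G1/S list (adjusted p = 1.22e-08; adjusted p = 0.0734 with an estimated correlation). The mean of the G2/M list was above 0 and those of the G1/S and p53 lists below 0 in 6 of 6 numbered high-low pairs, where an exact two-sided sign-flip test gave its smallest possible p, 0.0312 (adjusted p = 0.196 over 44 lists).

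**Figure D1:**
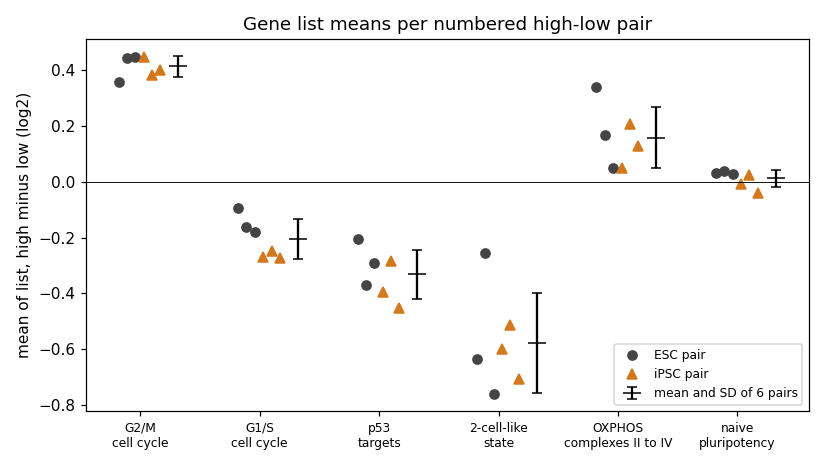
Mean log2 difference, high minus low potential, over the measured members of 6 gene lists (vertical axis, log2), for each of 6 numbered pairs of arrays (circles, ESC; triangles, iPSC), with mean and SD of the pairs beside them. The G2/M mean was above 0 in 6 of 6 pairs, and the G1/S, p53 and 2-cell-like means were below 0 in 6 of 6.

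Among mitochondrial and metabolic lists, the nuclear subunits of OXPHOS complexes II to IV, counted together with cytochrome c, were the group that the camera test called over both cell types. Of 22 measured members 1 rose (2 when adjusted over the list alone), with a median of 0.13 (adjusted p = 0.00235, limma's camera; adjusted p = 0.55 with an estimated correlation). The member that rose was Cycs, cytochrome c, at 0.82 ± 0.18 (adjusted p = 0.0311, limma), and the cytochrome c oxidase subunit Cox7b was at 0.50 ± 0.12 (adjusted p = 0.0516, limma). Camera made no call for complex I (33 measured, 0 changed), ATP synthase (10 measured, 0 changed), the TCA cycle (19 measured, 0 changed), glycolysis (19 measured, 0 changed) or fatty acid oxidation (16 measured, 0 changed). Genes of mitochondrial fusion, fission and mitophagy (15 measured, 0 changed) were not called either (adjusted p = 0.109, limma's camera), though their mean was below 0 in 6 of 6 pairs (-0.08 ± 0.03, SD; exact sign-flip p = 0.0312, adjusted p = 0.196). The mean of WNT and beta-catenin targets (13 measured, 0 changed; adjusted p = 0.272, camera) was above 0 in 6 of 6 pairs (0.14 ± 0.08, SD) with equal exact p-values, as were those of the OXPHOS II to IV list, while the 2-cell-like mean was below 0 in 6 of 6. In the list of mitochondrial biogenesis and DNA upkeep, 1 of 16 members rose, Polg2, the accessory subunit of the mitochondrial DNA polymerase (0.84 ± 0.16), and 1 rose and 4 fell when adjusted over the list alone. Tfam, which packages mitochondrial DNA, was at -0.29 ± 0.10 (adjusted p = 0.158, limma), and the coactivator Ppargc1a at -0.14 ± 0.08 (adjusted p = 0.467, limma). Of 11 transporters in the list of efflux pumps, 1 fell. This was Abcb1b, a P-glycoprotein that exports cationic compounds, at -0.93 ± 0.20 (adjusted p = 0.0285, limma), while its paralog Abcb1a was at -0.20 ± 0.11 (adjusted p = 0.44, limma) and Abcg2 at -0.06 ± 0.11.

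Genes of the naive pluripotent state did not pass the test (19 measured, 0 rose and 0 fell; median -0.02). The core factors Pou5f1 (-0.11 ± 0.08), Nanog (-0.06 ± 0.06) and Sox2 (-0.12 ± 0.07) differed by less than the threshold requires. The same held for the markers of exit from that state Otx2 (0.03 ± 0.43) and Fgf5 (0.18 ± 0.11). Of the genes of the fixed set, Abcb1b passed over both cell types, and none passed within ESC or within iPSC. The 2-cell-like list, genes of a rare state that resembles the 2-cell embryo, was lower in high-potential cells (median -0.29; adjusted p = 0.00468, limma's camera; adjusted p = 0.515 with an estimated correlation). Of its 15 measured members 1 fell (4 when adjusted over the list alone). Zscan4e fell by 3.37 ± 0.59 (adjusted p = 0.00958, limma), from 5.56 ± 1.87 (SD) in ESC low to 2.16 ± 1.32 in ESC high and from 5.47 ± 0.87 in iPSC low to 2.12 ± 0.62 in iPSC high. Signal may be shared with its near-identical relatives: Zscan4d was at -1.09 ± 0.37 (adjusted p = 0.165, limma) and Zscan4c at -1.11 ± 0.50 (adjusted p = 0.312, limma). Lists of mesoderm (24 measured, 0 changed) and neural genes (19 measured, 0 changed), and of fibroblast genes as a check for other cells (23 measured, 0 changed), gave no call. In the blood and macrophage list 1 of 14 members rose, the macrophage-associated lysosomal Cd68 (0.82 ± 0.09; adjusted p = 0.000828, limma), and the list was not called.

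In all, 403 probe sets were higher and 228 lower in high-potential cells over both cell types. The largest rises under the naming rule were the histone genes H3c14 (1.99 ± 0.21) and H3c15 (1.88 ± 0.17), which encode the same histone and may share probe signal. They were followed by Lsmem1 (1.74 ± 0.28), the membrane repair protein Trim72 (1.63 ± 0.27), the ubiquitin-conjugating variant Ube2v1 (1.62 ± 0.29), the netrin Ntn3 (1.51 ± 0.12), Plac8l1 (1.44 ± 0.16) and the growth factor Fgf18 (1.37 ± 0.19). The rise of H3c14 and H3c15 did not extend to the list of replication-dependent histones, which was not called (adjusted p = 0.758, limma's camera). Of its 11 measured members 1 rose and 0 fell over both cell types, 5 were above 0, and the median was -0.02. That list was not called within ESC or within iPSC either. After Zscan4e, the largest falls were Pramel19 (-2.38 ± 0.41), of a multicopy family in which the copy is uncertain, the costimulatory ligand Cd80 (-1.70 ± 0.26), Mrps36, a mitochondrial protein (-1.32 ± 0.21), the epoxide hydrolase Ephx1 (-1.19 ± 0.26), Pramel18 (-1.13 ± 0.21), Got1l1 (-1.06 ± 0.15) and the proton pump subunit Atp4b (-1.02 ± 0.22). Pramel18 was dim in all groups, from 2.20 ± 0.55 (SD) to 1.14 ± 0.20 in ESC and from 2.26 ± 0.64 to 1.06 ± 0.16 in iPSC. The arrays' lower quartile averaged 2.12 to 2.19 per group. With the replicate block within cell types, 523 probe sets were higher and 417 lower, and centring each array on its median gave 361 higher and 368 lower, which moved the share of higher calls from 63.9% to 49.5%. The count of lower probe sets dropped to 135 without ESC low replicate 2, 143 without ESC high replicate 2, 119 without ESC high replicate 3 (higher: 261), 143 without iPSC low replicate 3, 125 without iPSC low replicate 4, 132 without iPSC high replicate 3 and 118 without iPSC high replicate 4.

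Within ESC alone, 10 of 25 G2/M genes rose in the high fraction (18 when adjusted over the list alone). Among them were Ube2c (0.72 ± 0.08), Aurkb (0.72 ± 0.10), Nusap1 (0.68 ± 0.09) and Prc1, which bundles the central spindle (0.75 ± 0.11). Trp53inp1 (-0.77 ± 0.14) was the p53 target that fell (7 of 21 when adjusted over the list alone), and Ccne2 (-0.67 ± 0.13) the G1/S gene that fell. Rb1, the retinoblastoma protein that restrains S-phase entry, fell by 0.62 ± 0.09. Camera called the G2/M list (adjusted p = 4.99e-30; adjusted p = 0.0448 with an estimated correlation), p53 targets (adjusted p = 2.62e-08; adjusted p = 0.155 with an estimated correlation) and G1/S genes (adjusted p = 0.000306; adjusted p = 0.34 with an estimated correlation). It also called hypoxia and HIF target genes as lower (22 measured, 0 changed, 5 fell and 1 rose when adjusted over the list alone; median -0.20; adjusted p = 4.59e-05; adjusted p = 0.192 with an estimated correlation). In that list the collagen prolyl hydroxylase P4ha2 was at -0.68 ± 0.17 and Ndrg1 at -0.66 ± 0.18, neither past the threshold. The OXPHOS II to IV list (median 0.16; adjusted p = 0.000385; adjusted p = 0.599 with an estimated correlation) and the mitochondrial ribosome (56 measured, 0 changed; median 0.05; adjusted p = 0.0224; adjusted p = 0.681 with an estimated correlation) were called as higher. The 2-cell-like list was called as lower (15 measured, 0 changed, 1 fell when adjusted over the list alone; adjusted p = 0.0356; adjusted p = 0.681 with an estimated correlation). The ribosome call was lost without ESC low replicate 2 (adjusted p = 0.115, limma's camera), ESC low replicate 3 (0.153) or ESC high replicate 4 (0.207). The 2-cell-like call was lost without ESC low replicate 2 (0.228), ESC low replicate 4 (0.291), ESC high replicate 3 (0.251) or ESC high replicate 4 (0.0573).

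The ESC comparison held 77 higher and 13 lower probe sets, or 146 and 31 with the replicate block. The largest rises were H3c14 (2.10 ± 0.29), H3c15 (2.01 ± 0.23), Ntn3 (1.59 ± 0.17), the taste receptor Tas2r108 (1.45 ± 0.22), Plac8l1 (1.42 ± 0.23), the epoxide hydrolase Ephx3 (1.41 ± 0.16), the chemokine receptor Ccr4 (1.34 ± 0.21) and Adig (1.30 ± 0.21). Of these, Tas2r108 went from 2.11 ± 0.26 (SD), near the mean lower quartile of the ESC low arrays (2.14), to 3.56 ± 0.26, near the array medians. The largest falls under the naming rule were Got1l1 (-1.09 ± 0.21), Pramel11 (-0.91 ± 0.15, copy uncertain), the noncoding Snhg20 (-0.79 ± 0.15), the homeobox gene Nkx2-9 (-0.78 ± 0.13) and Fam221a (-0.69 ± 0.10), besides Trp53inp1, Ccne2 and Rb1. Pramel11 was dim, at 2.20 ± 0.29 (SD) in ESC low and 1.29 ± 0.14 in ESC high. In iPSC it was at 1.99 ± 0.17 in the low and 2.21 ± 0.17 in the high fraction. A fit to the 6 ESC arrays alone gave 36 and 3. The counts were 17 and 2 without ESC low replicate 2, 18 and 1 without ESC high replicate 2, 35 and 5 without ESC low replicate 4, 39 and 4 without ESC high replicate 3, and the lower count was 6 without ESC high replicate 4 and 8 without iPSC low replicate 3.

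In iPSC, 10 of 25 G2/M genes rose in the high fraction (18 when adjusted over the list alone). Among them were Aurka (0.87 ± 0.12), the kinetochore protein Cenpf (0.77 ± 0.11), Nusap1 (0.73 ± 0.09) and Ube2c (0.70 ± 0.08). Of 21 p53 targets, 4 fell (12 when adjusted over the list alone): Trp53inp1 (-1.05 ± 0.14), Phlda3 (-0.77 ± 0.15), Ccng1 (-0.69 ± 0.13) and Zmat3 (-0.56 ± 0.11; adjusted p = 0.0463, or 0.0579 with the replicate block, limma). Of 21 G1/S genes, 3 fell (7 when adjusted over the list alone): Ccne2 (-0.82 ± 0.13), Ung (-0.67 ± 0.13) and Cdc6 (-0.59 ± 0.11). Camera called the G2/M list (adjusted p = 4.04e-22), p53 targets (adjusted p = 9.37e-10) and G1/S genes (adjusted p = 3.36e-09), each with an adjusted p = 0.0668 with an estimated correlation. The 2-cell-like list was called as lower (0 changed, 2 fell when adjusted over the list alone; adjusted p = 0.0178; adjusted p = 0.54 with an estimated correlation), a call lost without iPSC low replicate 2 (0.0979) or iPSC high replicate 2 (0.0692). Apoptosis regulators (17 measured), endoplasmic reticulum stress genes (19 measured) and lysosome and autophagy genes (21 measured) were called as lower with 0 members changed and medians of -0.14, -0.08 and -0.08. Each had an adjusted p = 0.0473 from limma's camera, or adjusted p = 0.191, 0.606 and 0.472 with an estimated correlation. The arrays also differed in distribution, with a mean lower quartile of 2.12 in iPSC low and 2.19 in iPSC high. Whether other genes of similar level moved as much was not tested for these lists. All 3 calls were lost without ESC low replicate 3 (0.0521, 0.0554 and 0.0521), iPSC low replicate 2 (0.238, 0.230 and 0.0979), iPSC low replicate 4 (0.0527, 0.226 and 0.259) or iPSC high replicate 2 (0.113, 0.229 and 0.229). The reticulum and lysosome calls were also lost without ESC high replicate 3 (0.0529 each) or ESC high replicate 4 (0.0559 each), and the lysosome call without iPSC high replicate 3 (0.0573). Abcb1b was at -1.17 ± 0.28 in iPSC (adjusted p = 0.0877, or 0.0211 with the replicate block, limma) and at -0.69 ± 0.28 in ESC (adjusted p = 0.513, limma).

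The iPSC comparison held 88 higher and 50 lower probe sets, or 142 and 94 with the replicate block. Besides H3c14 (1.87 ± 0.29), H3c15 (1.76 ± 0.23), Plac8l1 (1.46 ± 0.23) and Ntn3 (1.42 ± 0.17), the largest rises were the receptor Gpr83 (1.55 ± 0.30), Fgf18 (adjusted p = 0.0289, limma), the cytokine Il11 (adjusted p = 0.0409, or 0.0511 with the replicate block, limma) and Gdpd2 (1.30 ± 0.19). Fgf18 went from 4.17 ± 0.46 (SD) in iPSC low to 5.67 ± 0.29 in iPSC high, and Il11 from 2.91 ± 0.28 (SD) in iPSC low to 4.27 ± 0.43 in iPSC high. The largest falls were Cd80 (-2.16 ± 0.37), Mrps36 (-1.72 ± 0.30), Ano3, of the anoctamin family (-1.55 ± 0.14), Eif4a3l1 (-1.53 ± 0.27, copy uncertain), Arap2 (-1.08 ± 0.20), Trp53inp1, Got1l1 (-1.03 ± 0.21) and Snhg20 (-0.95 ± 0.15). Eif4a3l1 was dim, from 2.49 ± 0.66 (SD) in iPSC low to 0.97 ± 0.09 in iPSC high, where the lower quartile of the arrays averaged 2.19. Median centring gave 70 higher and 85 lower, which moved the share of higher calls from 63.8% to 45.2%. The counts were 0 and 1 without iPSC high replicate 4, 9 and 4 without iPSC low replicate 4, 15 and 20 without iPSC low replicate 3, 26 and 11 without iPSC high replicate 3 and 39 and 21 without iPSC high replicate 2, and the higher count was 148 without iPSC low replicate 2.

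High minus low differences are called effects here, although cells were sorted by dye and potential was not changed. The effects in ESC and iPSC, which share no arrays, had a Pearson correlation across probe sets of 0.51 and a Spearman correlation of 0.36. Genes are not independent replicates, so these have no p-value from genes. Of 77 probe sets higher in ESC high and 88 in iPSC high, 45 were shared, where independent lists would share 0.269. Of 13 and 50 lower probe sets 8 were shared (0.0258 for independent lists), and 0 were called in opposite directions. The lists were not independent, since both calls of a probe set used the same variance estimate and genes vary together. The counts for independent lists are therefore a reference and not a test. In iPSC, 98.9% of the probe sets called in ESC had the same sign. In the test of the difference between the effects, 0 probe sets passed the adjusted threshold of limma, and the replicate block gave 1. An unadjusted limma p under 0.05 was held by 1100 of 25206, fewer than the share of 0.05 reached when nothing differs. The camera test of the difference called hypoxia and HIF targets, the mitochondrial ribosome, apoptosis regulators and G1/S genes, and none of these calls held with an estimated correlation.

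**Figure D2:**
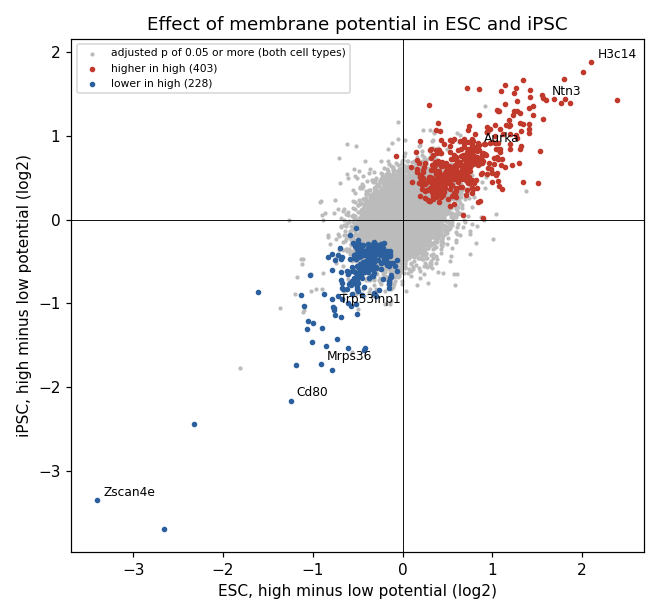
Log2 difference between high and low potential in ESC (horizontal axis) and in iPSC (vertical axis), 1 point per probe set. Red and blue points are the 403 higher and 228 lower probe sets over both cell types, and gray points did not pass. Zscan4e lies farthest along the lower diagonal among the genes named in the plot, and H3c14 at the upper end.

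Comparing iPSC with ESC, averaged over the fractions, 231 probe sets were higher and 493 lower in iPSC when the 12 arrays were taken as independent. Since the numbers pair the low and high arrays within a cell type, those counts rest on fewer independent units than arrays. With the replicate block as a random effect they were 143 and 320, and with the mean of each of the 6 pairs as 1 value 27 and 36. These fits cannot tell a cell type difference from a line difference, since the number of lines per cell type is not stated here. The largest rises were Pnma5 (2.26 ± 0.21), Dnajc5g (1.98 ± 0.18), the long noncoding RNA Lncenc1 (1.18 ± 0.17), the anion transporter Slco4a1 (1.14 ± 0.12), Spata31d1b (1.12 ± 0.14), the meiotic gene Hormad2 (1.10 ± 0.11), Tet3, which oxidises methylcytosine (1.04 ± 0.11), and the interferon-induced Oas1a (1.03 ± 0.14, copy uncertain). The largest falls were the checkpoint clamp gene Rad9b (-2.06 ± 0.11), the RNA-binding Rbm47 (-1.38 ± 0.27), Hsd17b11 (-1.31 ± 0.13), Dppa3, a maternal factor also expressed in naive cells (-1.20 ± 0.20), the glucuronidase Gusb (-1.16 ± 0.13), Tpst1 (-1.13 ± 0.11), Epp13 (-1.08 ± 0.14) and the ubiquinone synthesis enzyme Coq2 (-1.02 ± 0.13). Of these 8, Rad9b, Rbm47, Hsd17b11, Gusb, Tpst1 and Coq2 are on chromosome 5. Of the genes in this paragraph, none lost the call with the random effect. With pair means Lncenc1 (adjusted p = 0.0679, limma), Spata31d1b (0.0571), Oas1a (0.0645), Rbm47 (0.125) and Dppa3 (0.0782) lost it.

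Chromosomes 5 and 12 carried 368 of the 493 lower probe sets (74.6%) and 10 of the higher ones. Over expressed genes, the median iPSC minus ESC difference was -0.27 on chromosome 5 (91.5% of 555 genes lower) and -0.32 on chromosome 12 (95.1% of 346 genes lower). On the other chromosomes with over 1 expressed gene, medians lay between 0.0037 and 0.042. Relative to the mean of the ESC arrays, chromosome 5 medians averaged -0.27 ± 0.04 (SD, 6 iPSC arrays) and 0.00 ± 0.09 (6 ESC arrays), and those of chromosome 12 -0.32 ± 0.05 and 0.00 ± 0.01. On the other chromosomes 94 probe sets were lower and 215 higher in iPSC, and 31 and 6 had no chromosome in the reference table. The imprinted noncoding RNAs Meg3 (-0.37 ± 0.09; adjusted p = 0.0396, or 0.0701 with the replicate block as a random effect and 0.179 with pair means, limma) and Rian (-0.43 ± 0.07; adjusted p = 0.00581, or 0.0919 with pair means, limma), both on chromosome 12, fell by about as much as that chromosome's median.

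**Figure D3:**
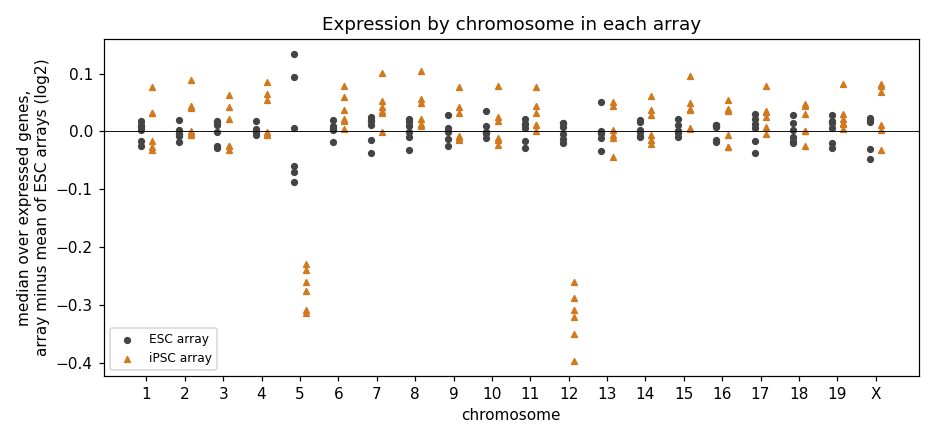
Median over the expressed genes of each chromosome (horizontal axis) of each array's log2 level minus the mean of the ESC arrays (vertical axis, log2), for 6 ESC arrays (circles) and 6 iPSC arrays (triangles). The iPSC arrays lie at -0.27 ± 0.04 (mean and SD) on chromosome 5 and -0.32 ± 0.05 on chromosome 12, below all ESC arrays.

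Among the lists, immediate early genes were higher in iPSC (22 measured, 1 rose, 9 when adjusted over the list alone; median 0.34; adjusted p = 3.91e-05, limma's camera; adjusted p = 0.478 with an estimated correlation). The orphan receptor Nr4a1 rose by 0.69 ± 0.08, and the growth factor-induced Egr1 was at 1.19 ± 0.31 (adjusted p = 0.0596, limma). Of 20 genes of the ATF4 stress response, 2 rose and 1 fell (8 and 1 when adjusted over the list alone; adjusted p = 0.000578, camera; adjusted p = 0.693 with an estimated correlation). The cysteine synthesis enzyme Cth (0.72 ± 0.08) and Nupr1 (0.72 ± 0.16) rose, and Psph, a serine synthesis enzyme encoded on chromosome 5, fell by 0.37 ± 0.08. Of 15 LIF and STAT3 targets, 2 rose (3 when adjusted over the list alone), the kinase Pim3 (0.43 ± 0.07) and the signalling inhibitor Spry2 (0.38 ± 0.07; adjusted p = 0.00876 for the list, camera; adjusted p = 0.336 with an estimated correlation). Of 18 cholesterol synthesis genes, 1 rose, the sterol reductase Tm7sf2 (0.33 ± 0.08; 4 when adjusted over the list alone; adjusted p = 0.0402 for the list, camera; adjusted p = 0.571 with an estimated correlation). The cholesterol call was lost without ESC low replicate 3 (0.0935), ESC high replicate 3 (0.0928) or iPSC low replicate 4 (0.105). In the naive pluripotency list, which was not called, Klf2 rose (0.39 ± 0.09) while Jam2 (-1.01 ± 0.15) and Dppa3 fell, and Nanog (0.08 ± 0.06) and Pou5f1 (-0.04 ± 0.08) did not pass. With the replicate block as a random effect, Psph (adjusted p = 0.0597, limma), Tm7sf2 (0.0858) and Klf2 (0.0609) lost the call. With pair means Psph (0.178), Tm7sf2 (0.121), Klf2 (0.190), Nupr1 (0.186), Pim3 (0.0893), Spry2 (0.106), Jam2 (0.0763) and Dppa3 (0.0782) lost it. Fits to 6 arrays gave 2 higher and 1 lower probe sets in the low fraction and 0 and 1 in the high fraction. The counts were 144 higher without ESC high replicate 3, 122 higher and 272 lower without iPSC high replicate 4, 305 lower without iPSC low replicate 2, 322 without ESC low replicate 4 and 324 without iPSC high replicate 3.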

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

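Although 0 single probe sets passed, the camera test called the high minus low difference unequal between iPSC and ESC in 4 gene lists. These were hypoxia and HIF targets (median difference 0.24, adjusted p = 0.000446, limma's camera; iPSC effect above ESC effect), the mitochondrial ribosome (median -0.07, adjusted p = 0.00914), G1/S genes (median -0.09, adjusted p = 0.0296) and apoptosis regulators (median -0.15, adjusted p = 0.0336). With an estimated correlation between genes the adjusted p-values were 0.372, 0.654, 0.654 and 0.372, so none of the calls held. In the hypoxia list, which kept its call with each array left out (highest adjusted p = 0.0302), the mean high minus low difference was -0.29, -0.08 and -0.37 in the 3 ESC pairs and 0.04, -0.04 and 0.03 in the 3 iPSC pairs. The mitochondrial ribosome call was lost in 3 of 12 cases, without ESC low replicate 2 (0.0859), ESC high replicate 4 (0.0559) or iPSC low replicate 4 (0.228). The G1/S call was lost in 6, without ESC low replicate 2 (0.0688), ESC low replicate 3 (0.0653), ESC high replicate 2 (0.154), iPSC low replicate 3 (0.0726), iPSC low replicate 4 (0.162) or iPSC high replicate 2 (0.248). The apoptosis call was lost in 7, without ESC low replicate 2 (0.108), ESC low replicate 3 (0.0653), ESC high replicate 2 (0.0563), ESC high replicate 3 (0.104), iPSC low replicate 2 (0.145), iPSC low replicate 4 (0.124) or iPSC high replicate 2 (0.173). No technical explanation was tested for these lists.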

How the results depend on the processing

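Leaving out chromosomes 5 and 12, the sign-flip test over pairs and the paired fits of iPSC versus ESC were chosen after seeing the data; the other alternatives were fixed before. No called value reversed. The replicate block within cell types gave 146 higher and 31 lower probe sets in ESC, 142 and 94 in iPSC, 417 lower over both and 1 for the difference between effects. Among named genes and lists it changed the calls of Il11, Zmat3, Cd68 (adjusted p = 0.0746, limma) and Abcb1b in iPSC and no other. For iPSC versus ESC, the replicate block as a random effect gave 143 and 320, and as 6 pair means 27 and 36. The block across cell types gave 6 lower in ESC. Without dim probe sets, 89 were lower in iPSC high and 347 higher in iPSC versus ESC. Median centring gave 85 lower in iPSC high and 368 lower over both. Array weights gave 152 higher and 91 lower in iPSC. The 6 ESC arrays alone gave 36 and 3. For iPSC versus ESC, the 6 low arrays gave 2 and 1, and the 6 high arrays 0 and 1. A fold change of at least 1.5 left 211 and 68 over both and 68 and 85 for iPSC versus ESC. An adjusted p under 0.01 left 23 and 1 in ESC, 4 and 2 in iPSC, 163 and 53 over both, and 68 and 152 for iPSC versus ESC. Without chromosomes 5 and 12, iPSC versus ESC gave 128 and 63. Stricter thresholds lower counts by construction, and for the others the cause was not tested.

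With each array left out, counts ranged from 17 to 98 higher and 1 to 18 lower in ESC, 0 to 148 and 1 to 63 in iPSC, 261 to 444 and 118 to 251 over both, and 122 to 236 and 272 to 444 for iPSC versus ESC. The count for the difference stayed at 0. The correlation between the effects ranged from 0.436 to 0.521, and was 0.675 among probe sets above the median level. The Spearman value was 0.36, and the highest Spearman value of the other drawn splits 0.281. Of 144 called values of named genes, 118 lost the call under at least 1 alternative, 71 of them with some array left out and 59 under other settings of the 12 arrays, the paired ones included, and 5 uncalled ones gained it. The G2/M call in ESC kept its side of the threshold under 24 of 24 alternatives. Over both it lost it under 1 of 24, the sign-flip test over 6 pairs (adjusted p = 0.196). That test gave the list the smallest p that 6 pairs can give, and adjustment over all lists raised it past the threshold. That loss therefore says nothing for or against the call. The p53 and G1/S calls in ESC and in iPSC, and the G2/M call in iPSC, lost it under 1 of 24, the estimated correlation. The p53 and G1/S calls over both lost it under 2 of 24, the estimated correlation and the sign-flip test, of which the latter again says nothing. The sign-flip test was run over both cell types only, so counts of losses within ESC or iPSC do not include it. Other list calls also lost it. The 2-cell-like list did so under 9 of 23 alternatives in ESC, 4 of 23 in iPSC and 3 of 23 over both. The mitochondrial ribosome in ESC did so under 5 of 24, and hypoxia targets in ESC under 1 of 24. OXPHOS II to IV lost it under 2 of 24 in ESC and 3 of 24 over both. For this list and the 2-cell-like list over both, the sign-flip test was among the losses, with the same limit. In iPSC, apoptosis regulators lost it under 9 of 24, endoplasmic reticulum stress under 12 and lysosome and autophagy under 14. For iPSC versus ESC, cholesterol synthesis lost it under 9 of 26, and the immediate early, ATF4 and LIF lists under 2 of 26 each. For the difference between effects, losses were 2 of 23 for hypoxia targets, 7 for the mitochondrial ribosome, 10 for G1/S genes and 11 for apoptosis regulators. The causes of losses other than those under the sign-flip test were not tested. The first residual component held 22.5% of the residual variance, under the 40% set for using it as a covariate, so that alternative was not run. RMA values hold no background measure, so which dim genes were expressed at all is unknown.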

Other observations

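The tests below of cell cycle order, of chromosome blocks and other chromosomes, of other microRNA genes, of Meg3, Rian and Mirg against the cluster and of its parts by position, and of all splits that respect the pairs were chosen after the results were seen; those of random lists and of drawn splits were set before.

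MicroRNA genes between Meg3 and Dio3, an imprinted cluster on chromosome 12, were higher in high-potential cells. This set was chosen after its values were seen. Of 51 measured, 32 rose and 0 fell over both cell types (median log2 difference 0.82), and 11 rose in ESC and 12 in iPSC. Mir369 rose by 1.52 ± 0.14 (SE, adjusted p = 0.000303, limma), Mir379 by 1.24 ± 0.10 (adjusted p = 0.000232) and Mir329 by 0.94 ± 0.09 (adjusted p = 0.00034). The 13 genes from Meg3 to the end of Rian had a median of 0.23 (2 rose), and the 38 beyond Rian a median of 0.86 (30 rose). The mean of the latter exceeded that of the former by 0.53 ± 0.24 (SD), in 6 of 6 pairs, where an exact sign-flip test gave its smallest possible p, 0.0312. The host transcripts Meg3 (0.28 ± 0.09, adjusted p = 0.131), Rian (0.15 ± 0.07, adjusted p = 0.316) and Mirg (0.48 ± 0.13, adjusted p = 0.0714) did not pass. Arrays of this kind probe the precursor sequence, so mature microRNA was not measured.

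A rise shared by all microRNA probe sets is argued against by the 487 other microRNA genes, whose median was 0.039. The 194 of them above a floor set near the cluster's lowest levels, with no upper limit, had a median of 0.085. Both medians lay below the cluster's lower quartile of 0.29. For the genes beyond Rian, a rise equal to that of Meg3 and Rian is argued against by their mean, which exceeded that of Meg3 and Rian by 0.65 ± 0.23 (SD), in 6 of 6 pairs. For the genes up to the end of Rian it stays open (0.12 ± 0.24, above 0 in 4 of 6 pairs). A rise of the genes beyond Rian equal to that of Mirg, which lies among them, is not settled: they exceeded it by 0.38 ± 0.29, in 5 of 6 pairs. A compressed response of the brighter Meg3 and Rian probe sets also stays open.

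In high-potential cells 17 of 25 G2/M genes rose and 4 of 21 G1/S genes fell over both cell types, and with an estimated correlation the list calls had adjusted p = 0.0495 and 0.0734, so the G1/S call was lost. Faster cycling of the whole high fraction that raised both lists is argued against by the G1/S mean, -0.20 ± 0.07 (SD over 6 pairs). Faster cycling that changes the lists unequally stays open, since cycle length was not measured. A shift shared by genes of equal signal level is argued against by 10000 random lists matched on level, whose highest mean was 0.091 against 0.41 for the G2/M list. The opposite signs, present in 6 of 6 pairs, are consistent with a larger share of G2 and mitotic cells in the high fraction. Whether dye content simply scales with cell size or mitochondrial mass through the cycle stays open, since neither was measured.

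Genes of chromosomes 5 and 12 were lower in iPSC than in ESC. A change of a few genes or of 1 region is argued against by the position blocks, where the lowest share of genes lower was 82.1%. The largest median shift of the other chromosomes was 0.042, so chromosomes 5 and 12 were lower relative to the rest of the same arrays. Quantile normalization in RMA largely removes a shift of the whole array, so this comparison could hardly have shown one. Medians below 0 in 20 of 20 blocks are consistent with a copy-number difference of whole chromosomes between the lines, and whether ESC gained or iPSC lost copies is not told by expression alone. The ESC arrays differed among themselves on chromosome 5 (-0.09 to 0.13) more than on chromosome 12 (-0.02 to 0.01), and in both fractions replicate 4 was highest.

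Splits of the same arrays asked whether arbitrary divisions of the samples give as many calls. Over both cell types, 1 of 100 drawn splits, the real one, gave as many as 631 probe sets, and the highest other gave 6. For the correlation of effects it was 1 of 100, with 0.513 against 0.392. Since the numbers pair the arrays, the 32 splits that part all 6 pairs were also run. Among these the real one alone reached its count and its correlation, a share of 0.0312. The highest other count was 0 and the highest other correlation 0.337. That share is the smallest that 32 splits can give, so they argue against chance without excluding it. For iPSC versus ESC, 1 of 100 drawn splits, which ignore the pairs, gave as many (724 against 1). Keeping the pairs together leaves 10 splits, too few for a share under 0.05 (724 against 0). For the difference between effects the real count was 0, which 100 of 100 splits reach whatever the data, so the splits say nothing on chance there. The highest other, 631, came from exchanging the fractions in 1 cell type, which turns the shared effect into a difference. Within ESC (90 against 0) and within iPSC (138 against 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Of those 10, 4 part all pairs, and the others of these also gave 0.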
